A study of Mus musculus with 12 samples.

How the data were processed

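Gene expression was measured in 12 samples of mouse embryoid bodies, aggregates in which embryonic stem (ES) cells differentiate. The cells were A2lox ES cells of the 129P2/OlaHsd background, a line built to carry a doxycycline (dox) responsive transgene. In the knockdown line dox turns on microRNAs against the transcript of Geminin (gene Gmnn), and in the overexpression line it turns on Geminin itself, per the labels. Dox was given at 0.5 µg/ml. The knockdown line received it from day 0 and was collected on day 4 (3 arrays with and 3 without dox). The overexpression line received it from day 3 and was collected on day 5 (replicates 1 and 2) or day 4 (replicate 3), with 1 array with and 1 without dox in each replicate. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

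Total RNA, 1 µg per sample, was converted to biotin-labelled sense-strand target and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array. The summarisation, background correction and normalization behind the deposited intensities are not given in the sources used here. Array means lay between 677.3 and 696.6 and array medians between 145.3 and 182.2, so the deposited intensities had been brought to a similar mean but not to a single distribution. Each array is 1 sample, and the number of arrays limits the precision.

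The values were transformed as log2(intensity + 1). Array medians on this scale spanned 0.324 (7.193 to 7.517), above the limit of 0.1 set in advance, so quantile normalization over all 35512 probe sets was the main setting. Fold changes are on this scale and understate the change of dim genes. The annotation table named 1 gene for 21789 probe sets and several genes for 1621, and left 12102 unnamed. The 21789 probe sets covered 19938 genes, of which 999 had more than 1 probe set. The brightest probe set over all arrays stood for such a gene. Of the 21789 probe sets, 21698 had a gene number found in the mouse RefSeq gene table (GRCm38.p6), and 0 symbols needed an update. That table was also used for the order of genes around Hprt. No coordinates are given, since no genome build is named for the array values. Genes whose mean lay below the 20th percentile (log2 value 6.46, signal 86.7) were not tested, which left 15950 genes.

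One model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It had a baseline for each line and day, 1 dox effect for each line, and no replicate block, which left 7 residual and 3.5 prior degrees of freedom. The contrasts were the dox effect in each line, their difference, their mean, and day 5 against day 4 in the overexpression line. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 15950 genes were called. Standard errors (SE) are those of the model. Day cannot be told apart from replicate 3 in the overexpression line. The day 4 pair of that line has no replicate of its own, and its values carry no test.

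Before the data were examined, 31 gene lists were fixed for pluripotency, germ layers, signalling pathways, the cell cycle, stress responses, chromatin complexes and feeder fibroblasts. Of 784 entries, 32 had no probe set of their own and are not analysed here. The lists were tested with camera in limma at a preset correlation of 0.01, which ranks a list against all other genes, with adjustment over the 31 lists. Camera with an estimated correlation and fry, which asks whether members move together beyond the spread between arrays, were run beside it. The SE of a list's mean shift comes from the spread of the list's mean between arrays in the same model. The list tests on the mean effect and on day were chosen after the data were seen. The genes named were fixed by rule. They are Gmnn, the 10 largest called changes in each direction for each line (5 for the other contrasts), or the 3 smallest p where none was called, and up to 4 members of a list with the largest change. Predicted gene models, olfactory, vomeronasal and small RNA genes were not named. Genes outside the rule are said to be so where they appear.

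For single genes, exact two-sided permutation tests were run over the arrays of a line, within day in the overexpression line. The smallest p they can give is 0.1 for 3 arrays against 3, and 0.167 in the overexpression line. The steps were tested on simulated arrays of 15950 genes with the means and gene-wise spread of the real ones. Of 50 genes changed 1.5-fold in the knockdown line, 23 were called, and 37, 50 and 49 of 50 at 2, 4 and 8-fold. In the overexpression line the numbers were 22, 43, 50 and 49, and for day 22, 42, 48 and 50. Among unchanged genes, 6, 11 and 16 were called. These simulated arrays held 200 changed genes per contrast and no shared variation between genes, unlike the real ones.

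The alternatives were a replicate block within each line or shared by both, deposited values centred on the array median or on the median of the tested genes, no filter or a filter at the 40th percentile, the mean of all probe sets of a gene, eBayes with trend and robust options, array weights, each line alone, day 5 alone, other thresholds, a pseudocount of 16, other list tests, and each of the 12 arrays left out. Quantile normalization over the 1-gene probe sets and list tests with the block were added after the data were seen. Of the unnamed probe sets and those of several genes, 0 were called by limma in any of the 4 dox contrasts, against 534 and 43 at an unadjusted p under 0.05 in the knockdown line. Figures were drawn with matplotlib 3.10.9.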

Results

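The arrays addressed whether lowering or raising Geminin, a nuclear protein that binds the replication licensing factor Cdt1 and also chromatin regulators, alters how embryoid bodies leave pluripotency and take up mesoderm and endoderm fates. Each of the 12 arrays gave 35512 probe-set intensities, and 15950 genes were tested. Levels are log2 intensities after quantile normalization.

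The targeted gene moved as the labels state in every pair of groups. In the knockdown line Gmnn (probe set 10408321) stood at 10.18 ± 0.14 (SD, n = 3) without dox and at 9.68 ± 0.06 (SD, n = 3) with dox, a log2 difference of -0.50 ± 0.14 (SE), or 1.41-fold lower. All 3 dox arrays lay below all 3 controls (exact two-sided permutation p = 0.1, the smallest possible). In the overexpression line Gmnn stood at 10.22 ± 0.10 (SD, n = 2) without and 11.10 ± 0.38 (SD, n = 2) with dox on day 5, and at 10.35 and 11.04 in the day 4 pair. The fitted log2 difference was 0.82 ± 0.14 (SE), or 1.76-fold, and all 3 dox arrays lay above all 3 controls (exact two-sided permutation p = 0.167, the smallest possible). After adjustment over all genes in limma neither difference was called (adjusted p = 0.965 in the knockdown and 0.922 in the overexpression line). For this gene alone the limma p was 0.00428 and 1.16e-04. Whether the probe set reads the transgene is not stated.

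**Figure D1:**
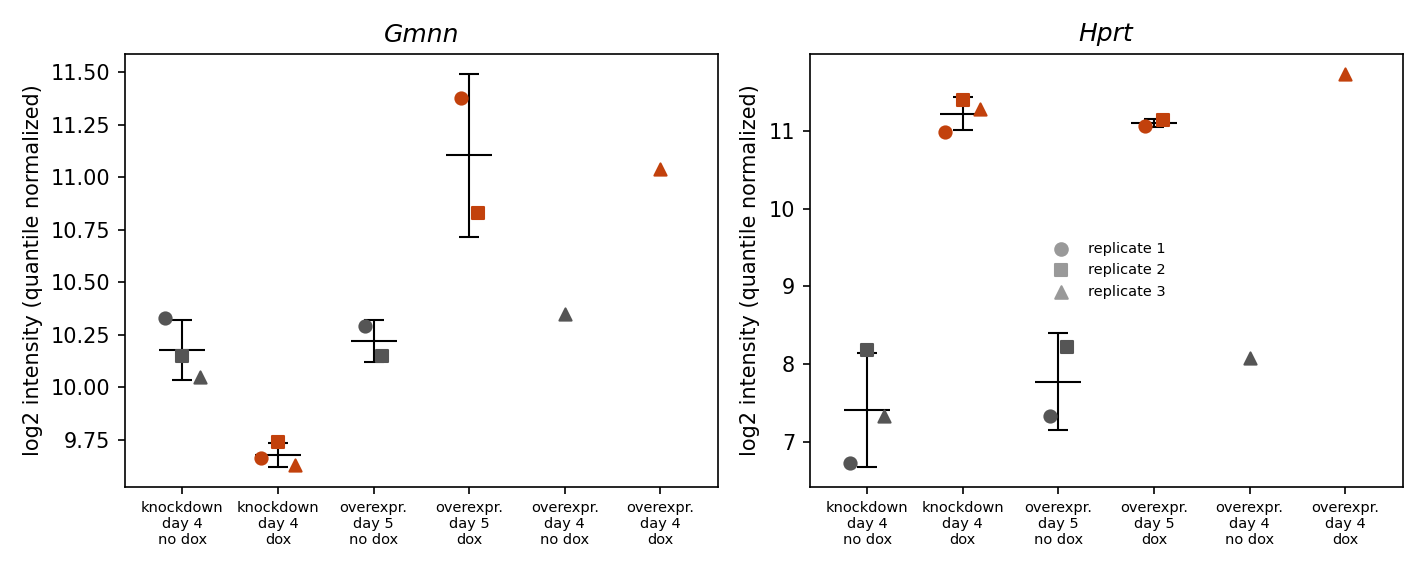
Log2 intensity of Gmnn and Hprt on each of the 12 arrays (vertical axes, which do not start at 0), by line, day and dox (horizontal axes), with bars for the mean ± SD of groups of 2 or 3 arrays and symbols for the replicate number. Gmnn is lower with dox in the knockdown line (9.68 against 10.18) and higher in the overexpression line (11.10 against 10.22 on day 5), and Hprt is higher with dox in both.

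The comparison with and without dox in the knockdown line asks which genes follow a lower Geminin level by day 4. Hprt (probe set 10599627), which encodes the purine salvage enzyme hypoxanthine phosphoribosyltransferase, rose from 7.41 ± 0.74 to 11.22 ± 0.21 (SD, n = 3 each). Its log2 difference was 3.81 ± 0.33 (SE), 14.1-fold (limma adjusted p = 0.00387, and 0.0744 with the arrays of that line alone). No other gene was called. At an unadjusted p under 0.05 there were 599 genes, 346 higher and 253 lower, where chance alone gives 798. With a replicate block within each line there were 1941, so this count depends on whether arrays of equal number are paired. No gene was called lower. The smallest p values in that direction belonged to Gzmn, a granzyme, at -0.51 ± 0.10, H2ac4, a histone H2A gene, at -0.41 ± 0.08, and Smim6 at -0.49 ± 0.11 (log2 ± SE; limma adjusted p = 0.965 for each).

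Lists of pluripotency and early germ layer genes were displaced in the knockdown line relative to all other genes, calls that were lost with an estimated correlation (adjusted p = 0.945 for each of 4 lists). Of 28 pluripotency genes, 23 were lower with dox and 5 higher (mean log2 difference -0.26 ± 0.30 SE; camera adjusted p = 0.00711). The largest differences were those of the nuclear receptor Nr0b1 (-0.91 ± 0.71), Zfp42 (-0.80 ± 0.23), also called Rex1, Esrrb (-0.74 ± 0.65) and Fbxo15 (-0.52 ± 0.50). Of 26 primitive streak and mesendoderm genes, 22 were higher (mean 0.41 ± 0.30; camera adjusted p = 6.85e-04), led by the homeobox gene Mixl1 (0.91 ± 0.77), the T-box factor Eomes (0.88 ± 0.56), Evx1 (0.82 ± 0.33) and Lhx1 (0.78 ± 0.68). This list did not pass fry with no block (adjusted p = 0.979). It passed fry with a replicate block within each line, chosen after the data were seen (adjusted p = 0.0306). The pluripotency and epiblast lists did not (fry adjusted p = 0.170 for each). The canonical Wnt target list had 19 of 23 members higher (mean 0.32 ± 0.22; camera adjusted p = 0.0013). It shares 10 of them with the primitive streak list, Mixl1, Evx1, Cdx2 (0.68 ± 0.35) and Fgf8 (0.67 ± 0.43) included, so it is not separate evidence. Epiblast genes were higher for 13 of 15 members (mean 0.23 ± 0.20; camera adjusted p = 0.041), with Wnt8a at 0.74 ± 0.49, Fgf5 at 0.54 ± 0.59, Sall2 at 0.30 ± 0.25 and Lef1 at 0.29 ± 0.21. Limma called 0 members over all genes and 0 when adjusted over the list alone, while 2, 3, 2 and 0 members of these lists, in that order, had an unadjusted p under 0.05.

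Visceral and primitive endoderm genes were lower in 25 of 28 cases (mean -0.23 ± 0.26; camera adjusted p = 0.0013, and adjusted p = 0.945 with an estimated correlation). Lama1, a basement membrane laminin, was at -0.66 ± 0.56, Sox7 at -0.56 ± 0.65 and Col4a1 at -0.49 ± 0.44. Foxa2, which definitive endoderm and axial mesendoderm also express, went the other way at 0.53 ± 0.36. All 24 genes of the integrated stress response, the amino acid and unfolded protein programme run by Atf4, were lower (mean -0.29 ± 0.37; camera adjusted p = 6.85e-04, and adjusted p = 0.945 with an estimated correlation), led by the glutathione-degrading enzyme Chac1 (-1.01 ± 0.54) and by Trib3 (-0.76 ± 0.64), Mthfd2 (-0.42 ± 0.55) and Sesn2 (-0.35 ± 0.39). Interferon response genes were higher in 12 of 16 cases (mean 0.14 ± 0.05; camera adjusted p = 0.0379, and adjusted p = 0.625 with an estimated correlation), with Oasl2 at 0.56 ± 0.15, Parp14 at 0.51 ± 0.18 and Ifit2 at 0.50 ± 0.18, whereas Xaf1 was at -0.40 ± 0.37. Limma again called 0 members, over all genes or over the list alone, while 0, 0 and 4 had an unadjusted p under 0.05. The SE of these means comes from a model of both lines that does not pair arrays by replicate number. Within replicates 1, 2 and 3, dox minus control was -0.22, -0.31 and -0.33 for the stress response list. It was -0.18, -0.21 and -0.30 for visceral endoderm and 0.11, 0.11 and 0.19 for interferon.

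The other 24 lists did not pass in the knockdown line. Nearest among those with a large shift for its SE was nascent and paraxial mesoderm, with 17 of 23 members higher (mean 0.15 ± 0.04; camera adjusted p = 0.0796). With a replicate block within each line it passed camera at the preset correlation (adjusted p = 0.00686), but not with an estimated correlation (adjusted p = 0.258). It also passed fry with this block, chosen after the data were seen (adjusted p = 0.0358), but not fry with no block (adjusted p = 0.321). Nodal and Activin targets share Mixl1, Eomes, Lhx1 and Fgf8 with the primitive streak list and also did not pass. Their mean was 9.55 ± 0.37 without and 9.86 ± 0.37 with dox (SD, n = 3 each; exact two-sided permutation p = 0.4). The neural ectoderm mean differed by -0.02 ± 0.06 over 39 genes, replication licensing and S phase by 0.05 ± 0.03 over 35, mitosis by 0.01 ± 0.04 over 30, and polycomb core by 0.01 ± 0.09 over 26. Feeder fibroblast genes, markers of the layer on which the ES cells had been kept, differed by 0.00 ± 0.08 over 25. Without replicate 2 of the controls all 7 list calls were lost (adjusted p from 0.189 to 0.727), Fgf5, Sall2, Sox7 and Col4a1 had the opposite sign, and without dox replicate 1 the stress response list alone passed (adjusted p = 0.0236). Of the 30 genes named for this line beside Gmnn, 19 shrank by over 1.5 times or turned without some array. Those were, besides the 4 that turned, Mixl1 (0.08), Eomes (0.28), Fgf8 (0.13), Cdx2 (0.34), Wnt8a (0.24), Lef1 (0.13), Fbxo15 (-0.14), Lama1 (-0.06) and Mthfd2 (-0.22) without control replicate 2, Nr0b1 (-0.51), Esrrb (-0.28), Lhx1 (0.23), Foxa2 (0.22) and Sesn2 (-0.20) without dox replicate 1, and Xaf1 (-0.01) without control replicate 3. The reverse occurred too: without dox replicate 2 Mixl1 was at 1.70, Eomes at 1.43 and Lama1 at -1.25. Leaving out 1 array leaves unequal replicate numbers with and without dox, so a difference between replicates enters the estimate. Across the 65 members of the pluripotency, primitive streak and Wnt lists, the dox effect correlated with the difference between replicates 1 and 2 of the overexpression line (Pearson r = 0.67, against 0.10 over all tested genes).

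**Figure D2:**
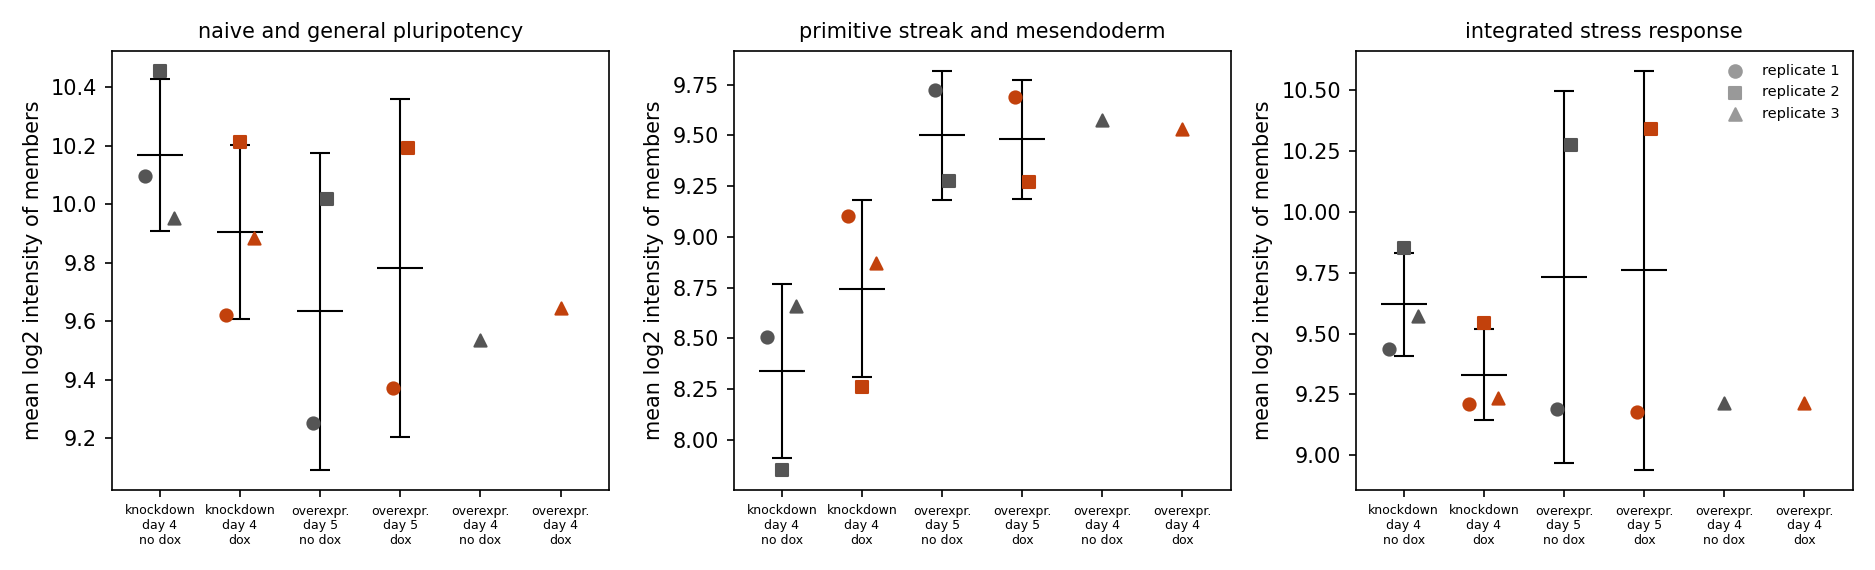
Mean log2 intensity of the members of the pluripotency (28 genes), primitive streak (26) and integrated stress response (24) lists on each array (vertical axes, which do not start at 0), by line, day and dox (horizontal axes), with symbols for the replicate number and bars for the mean ± SD of groups of 2 or 3 arrays. In the knockdown line the pluripotency mean is 10.17 ± 0.26 without and 9.90 ± 0.30 with dox (exact two-sided permutation p = 0.4).

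The comparison in the overexpression line asks which genes follow a raised Geminin level between day 3 and collection. Hprt was again the only gene called, with a log2 difference of 3.44 ± 0.33 (SE), 10.9-fold (limma adjusted p = 0.0105). It rose from 7.78 ± 0.63 to 11.11 ± 0.05 (SD, n = 2 each) on day 5 and stood at 8.08 and 11.74 in the day 4 pair. At an unadjusted p under 0.05 there were 149 genes, 55 higher and 94 lower, where chance gives 798. With a replicate block within each line there were 572. The fit with no block counts differences between replicates as spread, and day 5 arrays of equal number varied together (r = 0.79 after removing group means). So a count below chance does not show that few genes respond to dox. No gene was called lower. The smallest p values in that direction were those of Mettl11b (-0.37 ± 0.09), the forkhead gene Foxd2 (-0.42 ± 0.11) and Dpf3 (-0.68 ± 0.18), a subunit of the BAF chromatin remodelling complex (limma adjusted p = 1 to 2 decimals for each). With the arrays of that line alone Hprt was not called (limma adjusted p = 0.071), nor with day 5 alone or without either day 4 array (3.33, limma adjusted p = 0.261), nor without day 5 control replicate 1 (0.0855), dox replicate 1 (0.0885) or dox replicate 2 (0.105).

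In this line 7 lists passed, and each call was lost with an estimated correlation (adjusted p = 0.967 for each). Pluripotency genes were higher for 26 of 28 members (mean 0.13 ± 0.30; camera adjusted p = 0.0457), with Zfp42 at 0.31 ± 0.23, Klf4 at 0.30 ± 0.28 and Fbxo15 at 0.29 ± 0.50. Genes of the p53 and DNA damage response were higher in 20 of 23 cases (mean 0.13 ± 0.09; camera adjusted p = 0.00115), with the kinase gene Plk2 at 0.32 ± 0.21, Phlda3 at 0.25 ± 0.14 and Gadd45a at 0.24 ± 0.20. Interferon response genes were higher for 12 of 16 members (mean 0.08 ± 0.05; camera adjusted p = 0.0457), with Oas2 at 0.26 ± 0.14 and Parp14 at 0.21 ± 0.18, while Oas1a was at -0.23 ± 0.17. Knockdown-line arrays enter this effect only through the shared spread. Leaving out 1 of several of them still ended the interferon call (camera adjusted p from 0.05004 to 0.0647). Definitive endoderm genes were lower in 19 of 25 cases (mean -0.12 ± 0.20; camera adjusted p = 0.00115), with the Nodal antagonist Cer1 at -0.40 ± 0.56, Emb at -0.32 ± 0.23 and Lhx1 at -0.30 ± 0.68. Hypoxia and glycolysis genes were lower in 22 of 25 cases (mean -0.12 ± 0.19; camera adjusted p = 0.00115), with Aldoc at -0.41 ± 0.39, P4ha1 at -0.32 ± 0.45 and Ndrg1 at -0.27 ± 0.22.

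Lateral and extraembryonic mesoderm genes were lower for 16 of 22 members (mean -0.07 ± 0.19; camera adjusted p = 0.0457), among them Prrx1 (-0.36 ± 0.20), Bmp2 (-0.34 ± 0.18) and Kdr (-0.27 ± 0.28), the receptor that marks haemangioblast mesoderm. Haematopoietic and endothelial genes were lower for 19 of 26 (mean -0.06 ± 0.17; camera adjusted p = 0.0457), with Fli1 at -0.22 ± 0.22 and Flt1 at -0.21 ± 0.27. Limma called 0 members of these 7 lists, over all genes or over the list alone, and 0 had an unadjusted p under 0.05. Every one of the 7 list calls was lost without some arrays: definitive endoderm without day 5 control replicate 1 (adjusted p = 0.939) or dox replicate 2 (0.658), p53 without either of these (0.052 and 0.436) or either day 4 array (0.106), hypoxia without day 5 replicate 2 of either group (at most 0.658) or either day 4 array (0.111), and interferon without any of 9 of the 12 arrays (at most 0.410). The pluripotency, lateral mesoderm and haematopoietic lists turned direction without 1 of 2 day 5 arrays, as did Cer1, Lhx1 and Fbxo15. As in the knockdown line, leaving out 1 array lets a difference between replicates enter the estimate. Within pairs of equal number the pluripotency mean with dox was 9.373 against 9.250, 10.190 against 10.017 and 9.645 against 9.536. The p53, interferon and definitive endoderm lists also kept their direction in every pair. Hypoxia went the other way in replicate 1, lateral mesoderm in replicate 2 and haematopoietic genes in replicate 3. Of the 24 genes named for this line beside Gmnn, 18 shrank by over 1.5 times or turned without some day 5 array. Besides the 3 that turned these were Aldoc (-0.03), P4ha1 (-0.03), Ndrg1 (-0.15), Gadd45a (0.04), Phlda3 (0.12) and Zfp42 (0.14) without dox replicate 2, Kdr (-0.02) and Bmp2 (-0.10) without dox replicate 1, Flt1 (-0.05), Emb (-0.06), Prrx1 (-0.21) and Parp14 (0.08) without control replicate 1, and Klf4 (0.04), Fli1 (-0.08) and Oas2 (0.13) without control replicate 2. Here too some grew when 1 array was left out, with Aldoc at -0.85 and P4ha1 at -0.61 without day 5 dox replicate 1. The primitive streak mean differed by -0.03 ± 0.30 and the Wnt target mean by 0.06 ± 0.22.

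**Figure D3:**
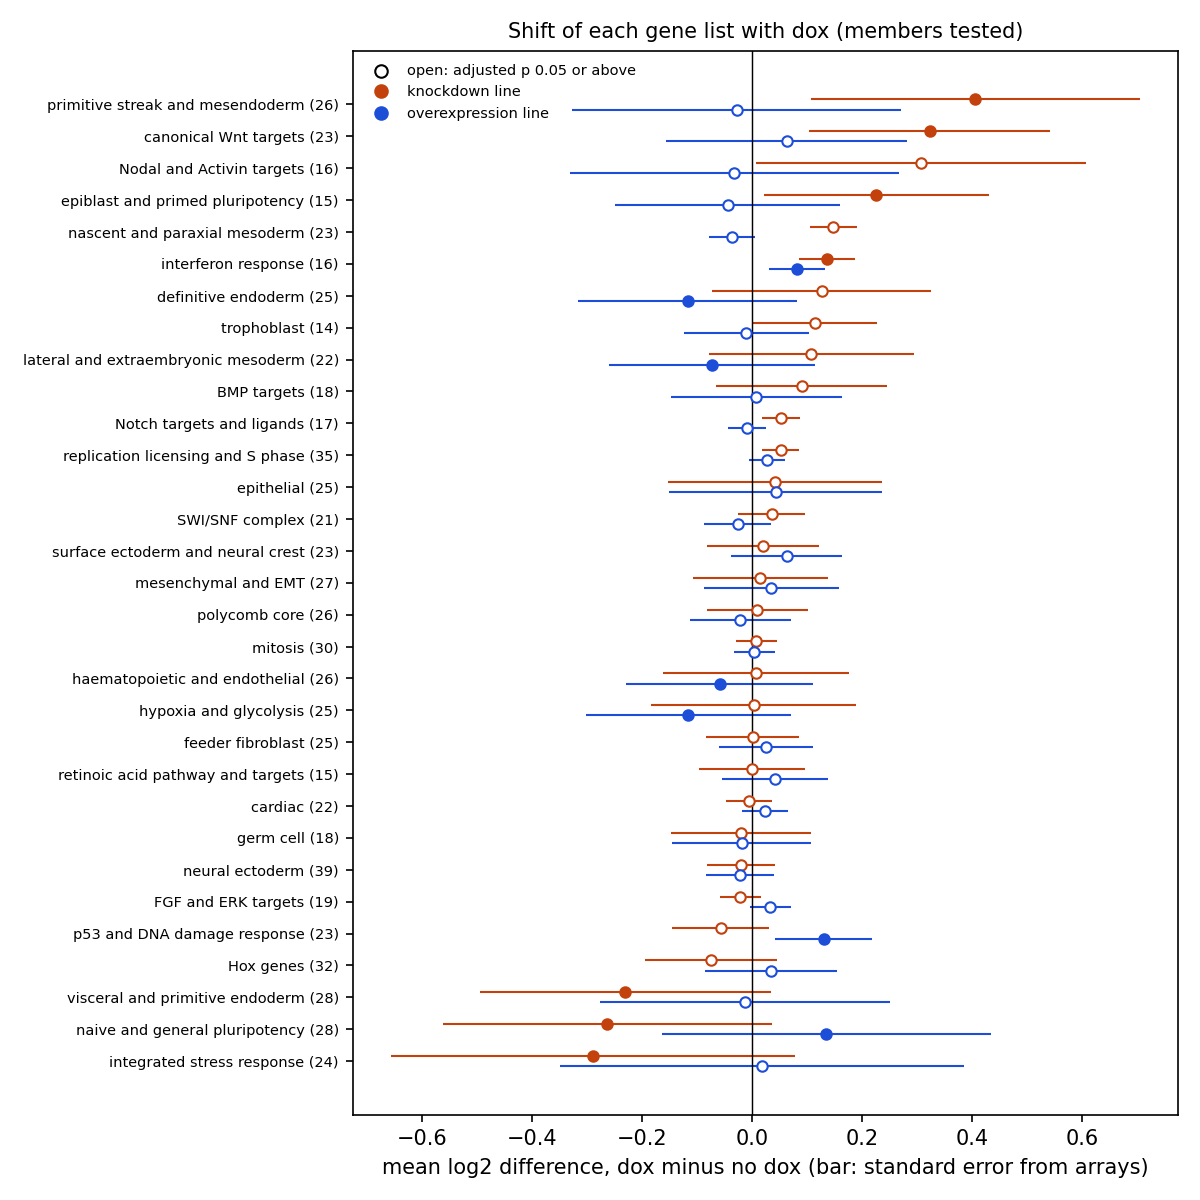
Mean log2 difference with dox (horizontal axis, bars for the SE between arrays) of the members of each of 31 gene lists (vertical axis, number of members in brackets) in the knockdown and the overexpression line. Filled points passed camera at a preset correlation, 7 in each line, and the error bars of 3 of these in the knockdown line and 5 in the overexpression line reach 0.

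Whether the dox effect differs between the lines was tested by subtracting the overexpression effect from the knockdown effect. A difference can come from 1 line alone, so it does not show opposite responses to less and more Geminin. The lines also differ in the day dox was started and in the day of collection. Gmnn itself differed by -1.32 ± 0.19 (limma adjusted p = 0.614 over all genes). Limma called 0 genes, with 340 at an unadjusted p under 0.05. Next to Gmnn, the smallest p values were those of the muscle gene Lmod3 (-0.51 ± 0.11), the complement gene C1qb (-0.71 ± 0.17), coagulation factor F5 (0.67 ± 0.16), Skp1 (0.54 ± 0.14) and Mrpl42 (0.93 ± 0.25), all with a limma adjusted p of 1 to 2 decimals. By camera 11 lists differed, 4 lower and 7 higher in the knockdown line, and all 11 calls were lost with an estimated correlation (adjusted p = 0.835 for each). Pluripotency genes differed by -0.40 ± 0.42 (camera adjusted p = 0.00185), with Nr0b1 at -1.16 ± 1.01 and Zfp42 at -1.11 ± 0.32. Primitive streak genes differed by 0.43 ± 0.42 (camera adjusted p = 0.00424), with Eomes at 1.19 ± 0.79 and Lhx1 at 1.08 ± 0.96. All 24 stress response genes were lower (mean -0.31 ± 0.52; camera adjusted p = 0.0125), with Chac1 at -0.90 ± 0.77, and 20 of 23 p53 response genes were lower (mean -0.19 ± 0.12; camera adjusted p = 0.00654), with Gadd45a at -0.53 ± 0.28. Nascent and paraxial mesoderm genes were higher by 0.18 ± 0.06 (camera adjusted p = 0.0483), with the retinoic acid hydroxylase Cyp26a1 at 0.87 ± 0.44 and Rspo3 at 0.70 ± 0.38. Each of the 11 calls was lost without 3 to 8 of the 12 arrays taken 1 at a time. Without day 5 dox replicate 2 Nr0b1 was at -0.37, Chac1 at -0.31 and Gadd45a at -0.33, without day 5 control replicate 1 Lhx1 was at 0.45, and without control replicate 2 of the knockdown line Eomes was at 0.59. Without day 5 dox replicate 1 Nr0b1 was at -1.86, Chac1 at -1.44 and Gadd45a at -0.77.

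Across the 15950 genes the dox effects of the lines were nearly uncorrelated (Pearson r = -0.041, Spearman rho = -0.088, and r = -0.089 without Hprt and Gmnn). Genes are not independent replicates, so no p is attached. The value went from -0.247 with day 5 alone to 0.224 with array weights. At an unadjusted p under 0.05 in both lines there were 12 genes, 6 with the same and 6 with the opposite sign, where independent lists would share 5.6. The lines share no control arrays.

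For the mean of the dox effects, Hprt was the only gene called (3.63 ± 0.23, limma adjusted p = 2.01e-04), and 273 genes had an unadjusted p under 0.05. Hprt was called in both lines, where independent lists of 1 gene would share 6.27e-05. With 1 gene a list, Fisher's exact one-sided p (6.27e-05) only restates the match. Both calls also use the same estimate of the spread of Hprt. None was called lower, the smallest p values being those of Smim6 (-0.34 ± 0.08), H2ac4 (-0.24 ± 0.06) and Mettl11b (-0.26 ± 0.07), with a limma adjusted p of 1 for each.

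Day 5 was set against day 4 within the overexpression line. Day 5 has the 4 arrays of replicates 1 and 2 and day 4 the 2 arrays of replicate 3, so the contrast sets 2 replicate numbers against 1, and day cannot be told apart from replicate. Limma called 89 genes, 63 higher and 26 lower on day 5. This fit counts the dox and control arrays of a replicate as separate samples. With a replicate block shared by both lines the count was 0. With a block within each line, where day is set against the spread within pairs, it was 1710. The signalling ligand Bmp5 rose by a log2 difference of 1.78 ± 0.29 (limma adjusted p = 0.0367), and the small heat shock protein gene Cryab by 1.62 ± 0.26, the retinoic acid synthesis gene Aldh1a2 by 1.52 ± 0.22, Capn6 by 1.51 ± 0.18 and Cyba by 1.35 ± 0.17. Tmem54 fell by 1.95 ± 0.26 (limma adjusted p = 0.0175), Fam131b by 1.36 ± 0.22, the de novo DNA methyltransferase gene Dnmt3b by 1.22 ± 0.22, Tcfl5 by 1.18 ± 0.16 and Mmp25 by 1.15 ± 0.21. All 22 lateral and extraembryonic mesoderm genes were higher (mean 0.83 ± 0.20; camera adjusted p = 3.63e-12, and adjusted p = 0.168 with an estimated correlation), and 12 passed when adjusted over the list alone. Tbx20 (1.25 ± 0.23) and Bmp2 (1.05 ± 0.19) were among those called over all genes, as were Foxc1 (0.90 ± 0.13), Shh (0.80 ± 0.14) and Tmprss2 (0.64 ± 0.11) of other lists. Epiblast genes were lower for 13 of 15 members (mean -0.53 ± 0.22; camera adjusted p = 5.03e-05, and adjusted p = 0.197 with an estimated correlation), 6 of them passing when adjusted over the list alone, with Dnmt3a at -0.66 ± 0.12. Replication licensing and S phase genes were lower for 34 of 35 (mean -0.25 ± 0.03; camera adjusted p = 2.65e-11, and adjusted p = 0.0953 with an estimated correlation), with the cyclin gene Ccne1 at -0.85 ± 0.12 and 1 member passing when adjusted over the list alone. Feeder fibroblast markers were higher on day 5 for 21 of 25 members (mean 0.27 ± 0.09; camera adjusted p = 9.79e-04, and adjusted p = 0.197 with an estimated correlation).

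For day 5 against day 4 in the overexpression line, centring on the median of the tested genes gave 39 called genes, 18 higher and 21 lower. This was in place of quantile normalization. Leaving out day 5 control replicate 1 or 2, day 5 dox replicate 2 or either day 4 array left few or no genes called for day. Arrays of the knockdown line enter this contrast only through the shared spread, yet leaving 1 out also moved the count. The genes called for day were 35 and 148 without control replicate 1 and 2 of that line. They were 37 and 15 without its dox replicate 1 and 3.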

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

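The tests of feeder markers and of the cassette for Hprt, and that of the share of a list shift kept without 1 array, were chosen after the result was seen. The 11 gene lists below and Gmnn stand here because their dox effects differed between the lines, the lists by camera at a preset correlation and Gmnn by its own limma p (3.85e-05). All 11 list differences were lost with an estimated correlation (adjusted p = 0.835 for each).

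The differences, knockdown minus overexpression effect on the log2 scale, were -1.317 for Gmnn and, as list means, -0.398 for pluripotency, 0.270 for epiblast, 0.434 for primitive streak and 0.185 for nascent mesoderm. They were 0.181 for lateral mesoderm, 0.244 for definitive endoderm, -0.217 for visceral endoderm, 0.260 for Wnt targets, -0.186 for the p53 response, -0.307 for the stress response and 0.119 for hypoxia and glycolysis. Of 100 splits of the arrays drawn from 200, 33 gave as many lists as the 11 of the real split, the highest other giving 20. These splits were drawn without regard to day or replicate number. The model keeps a baseline for each line and day, but differences between replicates enter the split effects. So chance is neither excluded nor shown by them for the number of lists. For genes limma called 0 in the real split (340 had an unadjusted p under 0.05), a count that 100 of 100 splits reach whatever the data, so this comparison decides nothing. The highest other split gave 922.

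Hprt was higher with dox in both lines, by 3.81 and 3.44. Spread of transcription along the X chromosome is argued against by its 10 nearest measured genes, whose median mean dox effect was 0.040 (SE 0.038). Feeder fibroblasts are argued against by their 25 markers, with a mean of 0.013 (SE 0.060). In A2lox cells the dox-responsive cassette lies beside Hprt, but the smaller effect of the lines, 3.440, only restates the pattern, and transcription from the cassette and an effect of dox itself cannot be told apart, as no cells without the cassette were treated. In each line 1 gene was called in the real split and 0 in the highest other of 10 splits (1 of 10 splits with as many), too few for a share under 0.05. For the mean effect 5 of 100 splits gave as many genes (1 real, 922 highest other). These splits were drawn without regard to replicate number, whose differences enter their effects, so by them the number of genes does not exclude chance. For Hprt itself all dox arrays lay above all controls in each line (mean effect 3.63, limma adjusted p = 2.01e-04).

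In the knockdown line the pluripotency list was lower and the primitive streak and Wnt target lists were higher with dox by camera at the preset correlation. These calls were lost with an estimated correlation (camera adjusted p = 0.945 for each). Leaving out 1 array kept at least 33.7 percent and at most 159.9 percent of each of the 3 mean shifts, so no array turned them. Without control replicate 2 the Wnt shift was 0.11, and what share this array sets cannot be told apart with 3 arrays a group. Across the 65 members the dox effect correlated with the difference between replicates 1 and 2 of the overexpression line (r = 0.67, bootstrap SD 0.08, against 0.10 over all tested genes). The 3 lists had passed in these data, and variation between cultures in the pace of differentiation or an effect of lower Geminin on the same genes could give this correlation. It does not decide between them, and all 3 pairs of equal number shifted in the direction of the mean. In the knockdown line 7 lists passed and 4 of 10 splits gave as many (highest other 11), and in the overexpression line 7 passed and 6 of 10 did (highest other 18), too few splits for a share under 0.05. These splits were drawn without regard to replicate number, nor to day in the overexpression line, where each day kept its own baseline. With an estimated correlation 0 lists passed in either line.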

How the results depend on the processing

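Of 1226 values of named genes under 19 other settings, 1181 kept their direction and side of the threshold, 42 kept the direction but lost the call, 3 gained a call and 0 turned. Of 767 values of gene lists, 521 kept both, 246 lost the call and 0 turned. With 1 array left out, 1109 of 1248 gene values and 451 of 588 list values kept both, 128 and 131 lost the call, and 11 and 6 turned. Among the named genes only Hprt and those named for day had been called in the main fit. For the other genes, staying uncalled counts as kept, so the gene shares do not measure how stable calls are. The 128 losses fell on Hprt in the overexpression line and on genes named for day. A group left with 1 array was assumed to vary like the others. Genes under a mean signal of 86.7 were not tested, so changes in dimmer genes are not covered. The cause of the changes below was not tested unless given.

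With the arrays of 1 line only, limma called 0 genes in either line, and with day 5 alone 0 in the overexpression line, where fewer arrays estimate the spread (Hprt kept 3.81 and 3.44 with its own line). Array weights gave 201 genes in the overexpression line (51 higher, 150 lower), 0.71 for Gmnn there (limma adjusted p = 0.00929) and 2567 genes for day. These weights were 5.57 for each of the 2 day 4 arrays of that line and 0.41 to 1.23 for the others, since 2 arrays without replicates are fitted closely, so these counts rest on 1 pair. For day, 33 genes were called after centring on the median of all probe sets, 39 after centring on that of the tested genes, 27 with no filter, 183 with trend and robust options and 322 at an adjusted p under 0.10, against 89. With 1 array left out, the range was 1 to 1 gene in the knockdown and 0 to 1 in the overexpression line, and 0 to 148 for day. The correlation of the dox effects ranged from -0.247 to 0.113 with 1 array left out and was 0.224 with array weights, within its jackknife SE of 0.335. Gmnn ranged from -0.56 to -0.42 and from 0.64 to 0.96.

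Of the gene lists, 0 passed in either line and 0 for the difference with an estimated correlation, and 0, 0 and 0 by fry. In the overexpression line 4 lists passed with no filter, 4 at the 40th percentile, 3 with array weights, 3 with the arrays of that line and 3 with day 5 alone, against 7. For the difference 5 passed at the 40th percentile and 6 with array weights, against 11. With 1 array left out, 1 to 8 lists passed in the knockdown line, 3 to 7 in the overexpression line and 1 to 10 for the difference. In the overexpression line the adjusted p ranged from 6.42e-06 to 0.658 for pluripotency, 1.15e-07 to 0.921 for lateral mesoderm and 2.31e-06 to 0.851 for haematopoietic genes, each turning direction without 1 of 2 day 5 arrays. Genes that turned ranged as follows in the knockdown line: Fgf5 -0.01 to 0.91, Sall2 -0.03 to 0.57, Sox7 -1.13 to 0.20, Col4a1 -0.96 to 0.02. In the overexpression line they were Fbxo15 (-0.16 to 0.74), Cer1 (-0.88 to 0.23) and Lhx1 (-0.89 to 0.32), and for the difference Trib3 (-1.43 to 0.05).

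A replicate block within each line called 1 gene in the knockdown line, 1 in the overexpression line and 1710 for day, and a replicate block shared by both lines 0 for day, against 89 with no block, where equal-numbered arrays count as separate samples. With camera at the preset correlation the replicate block within each line ended the call of the interferon list in the overexpression line (adjusted p = 0.158) and of hypoxia and glycolysis for the difference (0.083). It also brought nascent and paraxial mesoderm past the threshold in the knockdown line (0.00686). The interferon call in the overexpression line was lost in 12 of 17 other settings. At an unadjusted p under 0.05 the block within lines gave 1941 and 572 genes in the knockdown and overexpression line, against 599 and 149 with no block and 798 by chance. Every array of the knockdown line correlated best with the array of its own number (0.60, 0.44 and 0.05, after removing group means), as did those of day 5 in the overexpression line (0.79), a hint from the data only, since the third pair lies under 0.1 and the labels give no shared origin. Tests chosen after seeing the data, with this replicate block, passed 0 lists in either line and 0 for the difference with an estimated correlation. Fry with the block passed 6 in the knockdown line, 0 in the overexpression line and 2 for the difference. The 6 included primitive streak (fry adjusted p = 0.0306) and nascent and paraxial mesoderm (0.0358). Quantile normalization over the 1-gene probe sets, also chosen after seeing the data, moved no count of genes or lists by over 1.5 times.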

Other observations

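The list tests on the mean of the dox effects and on day, and the test of replicate numbers below, were chosen after the data were seen.

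For the mean of the dox effects 13 of 16 interferon response genes were higher (mean 0.11 ± 0.04 SE; camera adjusted p = 0.00283). The adjusted p with an estimated correlation was 0.187, and 0.625 and 0.967 in the knockdown and overexpression line, and the call was lost without control replicate 2 of the knockdown line (0.0514). In the overexpression line alone it was lost without any of 9 of the 12 arrays. Some of the 9 were knockdown-line arrays, which enter that effect only through the shared spread (camera adjusted p from 0.05004 to 0.0647). Oasl2, an antiviral oligoadenylate synthetase-like gene, was at 0.36 ± 0.11 and Parp14 at 0.36 ± 0.13. All 24 stress response genes were lower (mean -0.14 ± 0.26; camera adjusted p = 0.00351), as were 26 of 28 visceral endoderm genes (-0.12 ± 0.19; 0.00397), though in the overexpression line alone these list means were 0.02 ± 0.37 and -0.01 ± 0.26, with 14 and 18 members higher. Wnt targets were higher for 21 of 23 members (0.19 ± 0.15; 0.00258), primitive streak genes for 22 of 26 (0.19 ± 0.21; 0.0109, lost without 4 of the 12 arrays, and -0.03 ± 0.30 with 13 of 26 higher in the overexpression line alone) and replication licensing and S phase genes for 30 of 35 (0.04 ± 0.02; 0.0483). With an estimated correlation the adjusted p was 0.997 for these 5 lists. Without control replicate 2 of the knockdown line each of these 5 calls was lost (camera adjusted p from 0.0800 to 0.667). Of 100 splits of the arrays, 74 gave as many as the 6 lists of the real split (highest other 20). These splits were drawn without regard to day or replicate number. Each line and day kept its own baseline, but differences between replicates enter the split effects, so chance is neither excluded nor shown by them. With control replicate 2 of the knockdown line left out, 0 lists passed.

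Between day 4 (replicate 3) and day 5 (replicates 1 and 2) of the overexpression line 18 lists passed. Mesenchymal genes were higher on day 5 for 25 of 27 members (mean 0.39 ± 0.13; camera adjusted p = 4.96e-06), definitive endoderm for 19 of 25 (0.43 ± 0.21; 4.96e-06) and BMP targets for 17 of 18 (0.45 ± 0.17; 5.03e-05). Genes of FGF and ERK signalling were lower for 16 of 19 members (-0.22 ± 0.04; 3.80e-04) and Nodal targets for 13 of 16 (-0.24 ± 0.32; 0.0108). Stress response genes were higher on day 5 for 22 of 24 members (0.53 ± 0.39; 9.56e-05) and visceral endoderm genes for 22 of 28 (0.49 ± 0.28; 0.00256). With an estimated correlation 0 lists passed, the lowest adjusted p being 0.0953.

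The split of the arrays that called most genes (922) set replicate 1 of both lines, with and without dox, against replicate 2, which points to a structure of the samples that follows the replicate number. Across tested genes the difference between replicates 1 and 2 in the knockdown line correlated with that in the overexpression line (r = 0.54, and 0.79 over the members of the pluripotency, primitive streak and Wnt lists). The split had already called genes whose replicate difference is common to both lines, so this correlation largely restates it. Shared handling of both lines under 1 number, such as a day of culture, stays possible, but the labels do not give it. No biological explanation was tested. With a replicate block shared by both lines, limma called 1 gene for the mean dox effect, with 744 at an unadjusted p under 0.05.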
